A study of Mus musculus with 4 samples.

How the data were processed

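Whole-genome bisulfite sequencing had been done on hippocampal microglia of Tmem119-tdTomato+/- mice at postpartum week 3, in 2 control and 2 FGR libraries. Genomic DNA had been sonicated and bisulfite converted before sequencing, per the labels. The submitters' processing notes name Trim Galore 0.6.5, Bismark, whose version is not given in the sources used here, methylKit 1.28.0 and the genome build mm10. The parameters of these tools are not given in the sources used here. Each of the 4 deposited tables lists cytosines in CpG context, each strand apart. The coverage is a count of reads on the strand of the cytosine, per the file headers, and all deposited values are whole numbers. The methylation values are the percent of reads that read C or T, per the file headers. Coverage times percent gave a whole number of methylated reads within 0.02 reads for 100% of the listed cytosines. In every deposited table the lowest coverage is 5, so cytosines with fewer reads are missing, and which CpGs are listed depends on depth.

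The methylated reads of both strands were summed per CpG. In each library the 0.1% of CpGs with the highest coverage were left out. The 4 libraries kept 7909416, 8368314, 6668305 and 10680801 autosomal CpGs, in the order control 1, control 2, FGR 1 and FGR 2. Before this filter both strands were listed for 16.7%, 18.3%, 13.0% and 25.4% of CpGs. That share counts CpGs of the autosomes, chromosomes X and Y and mitochondrial DNA. Level means methylated reads over all reads of a region in 1 library, in percent, and a difference is FGR minus control of the group means in percentage points. Reads of a region are counted at each of its CpGs, so 1 read that covers several CpGs counts several times. Errors are the SD over n = 2. Confidence intervals for shares in single libraries are Wilson's 95% intervals and cover counting error only, since duplicate reads cannot be told from independent molecules here. They also take the counts of 1 read at several CpGs as independent, so they can be too narrow.

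Genes came from the RefSeq table of GRCm38.p6, the assembly of mm10, with 34328 protein-coding and lncRNA genes among 49997. The plan was to test promoters at annotated gene starts and to describe exons, introns and CpG islands. The table gives no strand, exon or island and no genome sequence was at hand, so both ends of each gene were tested in place of promoters, from 1500 bp outside to 500 bp inside, and bodies were taken between 500 bp inside each end. Autosomal tiles of 1000 bp, gene ends, gene bodies and single CpGs, and tiles of chromosome X, were compared between 2 control and 2 FGR libraries. A region needed at least 3 CpGs and 10 reads in every library, and a single CpG 10 reads in every library. Methylated and unmethylated reads were modelled by a quasi-binomial model with group as the only term. Its overdispersion was moderated across regions with squeezeVar of limma 3.58.1, with a trend on coverage, and kept at 1 or above. Calls needed a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 10 points. Global levels were compared by an exact permutation test over 6 assignments.

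The 14 gene lists, with 315 genes, were fixed beforehand, and 312 of these were found among the protein-coding and lncRNA genes. Both ends were measured for 173 of the list genes and the body for 280. Lists were tested with camera of limma at a preset correlation of 0.01 on log2 ratios of methylated to unmethylated reads with 0.5 added to each, adjusted over the lists. For ends, the less methylated of the 2 ends of a gene was used. Random lists were drawn 10000 times, matched on deciles of the number of CpGs for levels and on size alone for fry's test in either direction.

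Named tiles are the 8 largest rises and 8 largest falls among called tiles with at least 5 CpGs in each library and both FGR libraries beyond both controls, 63 tiles in all. With fewer than 10 gene ends or bodies called, the 6 with the smallest p in each direction are named, leaving out Gm and Rik symbols. Of the lists, up to 12 members with a called tile within 5000 bp and the 2 ends per list with the largest difference are named, besides 8 marker genes and 5 imprinted genes fixed beforehand.

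The tests were tested on simulated data with the coverage of these libraries and 50 regions changed by each of 20, 30, 40 and 60 points. Each simulated region had the same level whichever of its CpGs a library listed, so differing CpG lists were not simulated. With the same overdispersion in all regions, 2, 11, 24 and 48 of 50 changed tiles were recovered among 550656, and 2 of 87 calls were false. With overdispersion that varied between regions, 1, 11, 17 and 45 were recovered, and 44 of 118 calls, 37.3%, were false, so the adjusted p of tiles can be too small. On shared CpGs, 3, 0, 14 and 45 of the changed tiles were recovered among 145864 with equal overdispersion and 0, 2, 8 and 36 with varying overdispersion. Of gene ends 9, 38, 44 and 50 were recovered with equal overdispersion and 4, 27, 39 and 48 with varying overdispersion. For gene bodies, 47 and 41 were recovered at 20 points. Of single CpGs 18 and 23 were recovered at 60 points. The simulated overdispersion was near the 1.68 fitted to tiles for every kind of region. The libraries gave 2.44 for gene ends and 3.98 for gene bodies, so the recovery of ends and bodies is overstated. They gave 1.16 for tiles on shared CpGs and 1.10 for single CpGs, where recovery can be understated. With replicate number as a block no changed tile, end or site was recovered, so a count of 0 there carries no information. A simulated list of 30 genes moved by -5 points had a camera p of 1.04e-06 and an unmoved one 0.495.

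The alternatives were no overdispersion, as methylKit tests by default, other thresholds of difference, adjusted p and coverage, no filter on high coverage, thinning to the shallowest library, the replicate number as a block, each library left out in turn, limma on log ratios with and without centring, the methylation design of edgeR 4.0.16, other window sizes, only CpGs listed in all 4 libraries, and, for the autosomal level, CpG-dense sequence left out. Chromosome Y, mitochondrial DNA and other contigs were left out of the comparisons. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma, edgeR and statmod 1.5.0.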

Results

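DNA methylation at CpG sites was measured across the genome by bisulfite sequencing in microglia, the resident immune cells of the brain, taken from the hippocampus of mice at postpartum week 3. The mice carried a Tmem119-tdTomato allele, a red fluorescent reporter at a microglial gene. There were 4 libraries, 2 from control mice and 2 from mice with fetal growth restriction (FGR), and the comparison asked how growth restriction before birth relates to microglial DNA methylation. The labels do not say whether the replicates are separate animals or pools, so every test measures only the spread between these libraries. Control replicate 1 listed 9335713 cytosines with a summed coverage of 62202250 reads, and control replicate 2 listed 10023353 cytosines with 66971740 reads. FGR replicate 1 was the shallowest, with 7615146 cytosines and 49563150 reads, and FGR replicate 2 the deepest, with 13578464 cytosines and 91762720 reads. No listed cytosine had a coverage under 5, and the mean listed coverage lay between 6.51 and 6.76 reads. Both strands were summed per CpG, and 1419430 autosomal CpGs, 8.90% of those listed in any library, were listed in all 4. Numbers of reads are counts summed over cytosines, so a read that covers several CpGs counts at each of them. Levels are means of the libraries with the SD (n = 2). With 2 libraries against 2 there are 6 assignments, so a two-sided exact permutation test cannot go below p = 0.333 and cannot reach 0.05.

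The levels at marker genes gave a picture of the cells. The gene table gives no strand, so each gene has a low and a high end, named by coordinate, and the start of the gene can be either. At the high end of P2ry12, a purinergic receptor of microglia on chromosome 3, methylation was 1.59 ± 2.24% in control and 2.402 ± 0.587% in FGR over 63 to 151 reads per library. At the high end of Cx3cr1, the fractalkine receptor, it was 3.39 ± 0.864% and 1.51 ± 0.478%, and the body of Cx3cr1 had 22.6 ± 0.937% and 17.1 ± 1.59%. The body of Tmem119 had 38.8 ± 13.8% in control and 28.7 ± 6.80% in FGR, and its low end 60.3 ± 9.49% and 54.5 ± 16.5%. The body of Sall1, a transcription factor of microglial identity, had 35.6 ± 0.914% and 46.4 ± 9.63%, and that of Spi1, which encodes the myeloid factor PU.1, had 66.0 ± 8.17% and 63.7 ± 2.90%. Of the genes of other cell types fixed beforehand, the low end of Rbfox3, a neuronal marker, had 89.5 ± 4.67% and 85.7 ± 4.32%, and the high end of Gfap, an astrocyte intermediate filament gene, had 89.5 ± 1.42% and 62.0 ± 8.50%. The body of Mog, a myelin gene, had 74.97 ± 1.38% and 84.9 ± 5.86%. The ends of Sall1, Spi1 and Mog and the high end of Tmem119 were not measured in all 4 libraries. Imprinted genes have regions where 1 parental allele is methylated, and the gene table does not tell whether the measured ends lie in them. The high end of Peg3 had 51.2 ± 2.61% in control and 39.9 ± 5.70% in FGR. The low end of Mest had 57.3 ± 11.99% and 71.5 ± 6.28%, and the high end of Snrpn 52.6 ± 6.36% and 55.9 ± 6.30%. The low end of Plagl1 had 73.5 ± 14.1% and 56.7 ± 6.74%, and the high end of Kcnq1ot1 had 58.8 ± 15.7% and 41.9 ± 11.5%. None of these differences passed the test across genes.

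Autosomal methylation was slightly lower in both FGR libraries than in both controls. The level was 76.2 ± 0.268% in control and 75.1 ± 0.678% in FGR, a difference of -1.05 percentage points (n = 2 per group, two-sided exact permutation p = 0.333). The libraries of a group differed by 0.379 points in control and by 0.958 points in FGR. At the 1419430 CpGs listed in all 4 libraries the levels were 76.8 ± 0.108% and 76.4 ± 0.0193%, a difference of -0.387 points against gaps of 0.153 and 0.0273 points within the groups. At these shared CpGs the FGR mean was the lower on 19 of 19 autosomes, from -0.498 points on chromosome 17 to -0.179 points on chromosome 19, and both FGR libraries lay below both controls on 18 of them, all but chromosome 19. The autosomes come from the same 4 libraries and are not independent replicates. The difference was -0.470 points at gene ends, -0.371 points in gene bodies and -0.396 points between genes. It was -2.63 points in CpG-dense sequence, with 20 or more CpGs within 250 bp, where the controls had 62.2% and 62.9% and FGR replicates 1 and 2 had 57.9% and 62.0%, so that the gap of 4.05 points between the FGR libraries exceeded the difference. Without FGR replicate 1 the difference over all listed CpGs was -0.573 points, and at shared CpGs it was -0.373 points.

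**Figure D1:**
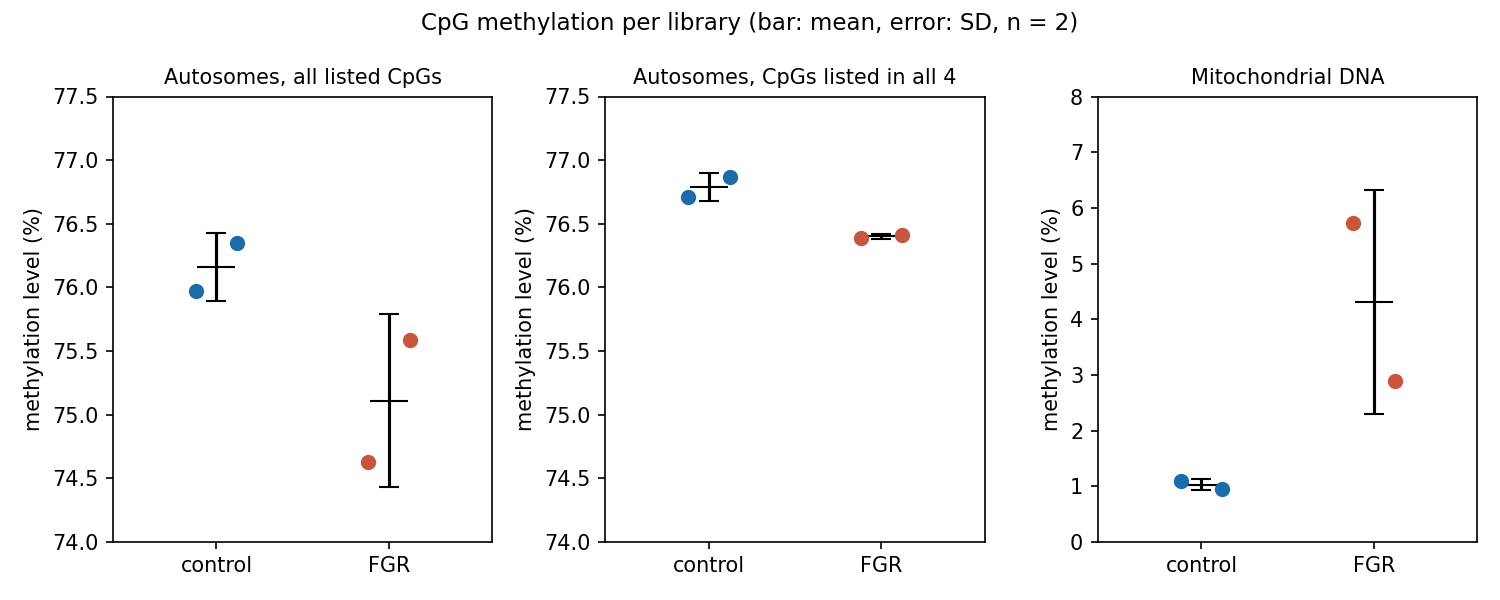
CpG methylation level in percent of each library (points), with group mean and SD (n = 2), for all listed autosomal CpGs, for autosomal CpGs listed in all 4 libraries, and for mitochondrial DNA. The group means are 76.2% and 75.1%, 76.8% and 76.4%, and 1.03% and 4.31% for control and FGR.

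Differences between the groups were next sought in windows (tiles) of 1 kb, which locate where the genome differed. In 162 of 550656 tiles the level differed between FGR and control by at least 10 points at an adjusted p under 0.05, 55 with a higher level in FGR and 107 with a lower level. On simulated data 2 of 87 or 44 of 118 tile calls were false, depending on how the spread between libraries was simulated. Libraries that list different CpGs of a tile were not simulated, so these shares do not give the share of false calls among the 162. Named here are tiles with at least 5 CpGs in each library; some called tiles with fewer CpGs differed by more. Among the named tiles the highest gain lay on chromosome 4 from 124987001 to 124988000, in Rspo1, which encodes a Wnt agonist, and overlapping Gm12930: the level was 20.1 ± 0.990% in control and 91.4 ± 7.59% in FGR (adjusted p = 0.00393). Gains of 67.1, 59.3 and 58.8 points lay in Hps6, a gene of lysosome-related organelles on chromosome 19 at 46004001, in Cfap300, a gene of cilia on chromosome 9 at 8042001, and in Il1rl2, the receptor of interleukin 36 on chromosome 1 at 40356001. Camkmt, a calmodulin methyltransferase gene on chromosome 17 at 85455001, and Chst2, a sulfotransferase gene on chromosome 9 at 95405001, had gains of 52.8 and 51.8 points. In Camkmt the level was 1.64 ± 2.32% in control and 54.5 ± 32.4% in FGR, and without FGR replicate 2 the gain was 29.9 points. Of the gains outside genes, a tile 89 bp from Tex37 on chromosome 6 at 70912001 was 56.8 points higher, and one 20226 bp from Gm41005 on chromosome 13 at 75797001 was 61.1 points higher.

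The deepest loss among tiles with at least 5 CpGs in each library lay on chromosome 2 from 25428001 to 25429000, at the low end of Abca2, which encodes a lipid transporter, where the level was 76.1 ± 5.50% in control and 3.10 ± 0.8997% in FGR (adjusted p = 0.000393). In Utrn, which encodes the dystrophin relative utrophin, the tile on chromosome 10 at 12836001 had 72.8 ± 15.5% and 3.00 ± 4.24%. The level fell by 64.8 points in Ttc21b, a gene of transport in cilia on chromosome 2 at 66210001, by 64.2 points in the zinc finger gene Zfp2 on chromosome 11 at 50916001, and by 63.6 points in Wdr1, a gene of actin filament disassembly on chromosome 5 at 38546001. It fell by 62.6 points in the transporter gene Slco5a1 on chromosome 1 at 12990001, and by 62.6 points in a tile 15471 bp from Fam136a on chromosome 6 at 86349001. The last of the 8 named losses, of -60.4 points, lay 13568 bp from Tex2 on chromosome 11 at 106627001. Of the genes in the fixed lists, Mbd2, which encodes a reader of methylated DNA, held a tile at -55.3 points on chromosome 18 at 70569001 (adjusted p = 0.0373), and Egln1, which encodes an oxygen-sensing prolyl hydroxylase, held a tile at -45.9 points on chromosome 8 at 124919001 (adjusted p = 0.0420). In each of these 18 tiles both FGR libraries lay beyond both controls, over 20 to 193 reads per library. For the 8 named gains and 8 named losses this was a condition for being named, so it is not a result. Groups did not overlap in 33.0% of all tested tiles, where chance gives 33.3%.

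The libraries mostly listed different CpGs of a called tile, and the differences were far smaller where the same CpGs were compared. In 152 of the 162 called tiles at least 1 CpG was listed in both groups, with a median of 4 such CpGs among 19 listed in either group. At those CpGs the median difference in the direction of the call was 6.38 points, against 55.7 points over all CpGs of the tile. In Rspo1 the 4 CpGs listed in both groups had 90% in control and 96.6% in FGR, in Abca2 the 3 such CpGs had 41.2% and 26.1%, and in Utrn the 6 such CpGs had 0% and 3.66%. In Mbd2 the 4 such CpGs had 33.3% and 21.4%, and the single one in Egln1 had 93.3% and 100%. Of the named tiles only that in Slco5a1 had enough CpGs listed in all 4 libraries to be tested on them, and its level there was -8.27 points lower (adjusted p = 0.923). Among 145864 tiles tested on shared CpGs, 1 was called, in Ccdc107 on chromosome 4 from 43493001 to 43494000, named after its values were seen. Summed over its 3 CpGs, 62.9% of 35 read counts were methylated in FGR replicate 1 and 4.76% of 21 in FGR replicate 2. In the controls it was 0% of 38 and of 15 read counts. Of the 162 tiles 11 could be tested on shared CpGs, and 0 of these were called. The count over all CpGs fell to 0 with limma, where 25243 tiles had an unadjusted p under 0.05, and to 0 with the replicate number as a block. The block recovered no changed tile on simulated data, so its 0 carries no information. The limma test of tiles was not run on simulated data. The number was 1716 without control replicate 1, 1805 without control replicate 2, 1558 without FGR replicate 1 and 1770 without FGR replicate 2.

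**Figure D2:**
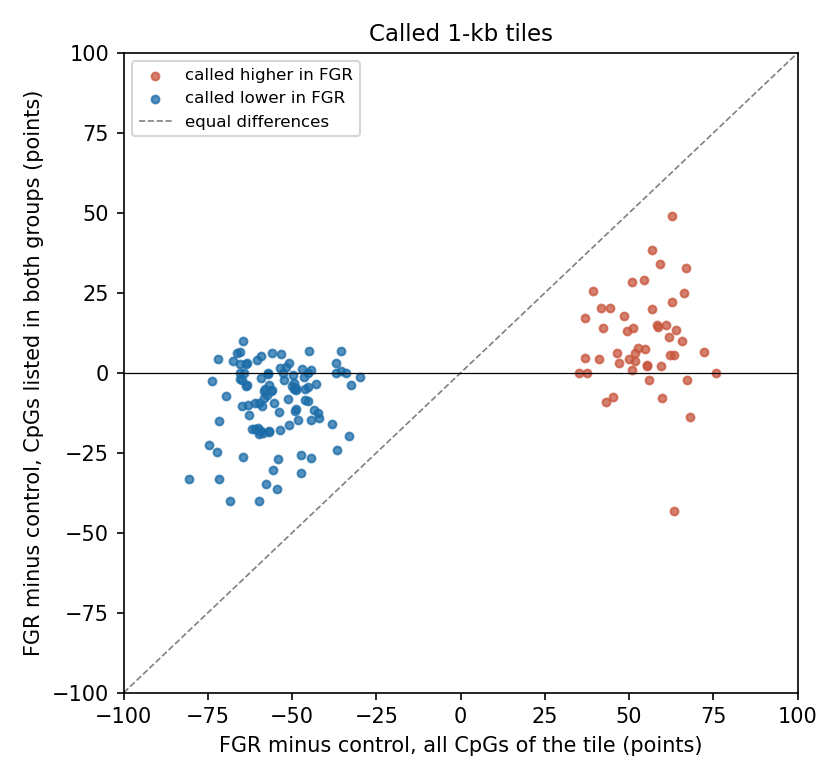
Difference between FGR and control in percentage points for the 152 called tiles with a CpG listed in both groups, over all CpGs of the tile (horizontal axis) and over the CpGs listed in both groups (vertical axis); points are tiles and the dashed line marks equal differences. The median in the direction of the call is 55.7 points on the horizontal axis and 6.38 points on the vertical axis.

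At the scale of gene ends, where promoters lie, no end passed the test. The quasi-binomial test called 0 of 46439 ends, with 2739 at an unadjusted p under 0.05, and limma and edgeR also called 0, with 2203 and 1949 at an unadjusted p under 0.05. The smallest adjusted p was 0.561, and it was shared by all of the following ends. Among the 6 ends with the smallest p and a higher level in FGR were the low end of Rxra, a retinoid X receptor gene on chromosome 2, with 14.6 ± 0.505% in control and 86.4 ± 9.0% in FGR, and the high end of Cry1, a circadian repressor gene on chromosome 10, with 0.373 ± 0.528% and 78.9 ± 22.0%. The low end of Cdc6, a DNA replication licensing gene, had 30.9 ± 4.41% and 85.0 ± 2.30%, and that of Qpct, a glutaminyl cyclase gene, 29.0 ± 2.13% and 92.9 ± 6.88%. The high ends of Tpbgl and Zswim4 differed by 65.8 and 41.8 points. Among the 6 with a lower level were the low end of Riox2, a histone and ribosomal oxygenase gene on chromosome 16, with 96.9 ± 0.535% and 24.9 ± 1.54%, and the high end of Ezh2, the histone methyltransferase gene of Polycomb on chromosome 6, with 87.7 ± 9.10% and 12.3 ± 2.08%. The high end of Cdo1, a cysteine dioxygenase gene, differed by -76.8 points and that of the zinc finger gene Zbtb12 by -61.7 points. The low ends of Ythdf3, a reader of methylated RNA, and of Rtn4rl1, a Nogo receptor relative, differed by -69.8 and -64.7 points. These 12 ends had 15 to 281 reads per library, and none had enough CpGs listed in all 4 libraries to be compared on them. Of 10354 ends tested on shared CpGs 1 was called, the low end of Ccdc107, which overlaps the tile named above and rests on FGR replicate 1. The count was 118 without FGR replicate 1 and 288 without FGR replicate 2, in fits where the lone library is assumed to vary like the others.

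Whole gene bodies were measured more deeply, and none passed the test either. The quasi-binomial test called 0 of 28013 bodies, with 1781 at an unadjusted p under 0.05, a smallest adjusted p of 0.692, and 0 calls by limma with 1582 at an unadjusted p under 0.05. The bodies with the smallest p and a higher level in FGR were those of Vsig10l with 41.5 ± 1.06% in control and 78.2 ± 2.55% in FGR, of the lysine methyltransferase gene Eef1akmt3 with 52.2 ± 5.10% and 82.3 ± 0.0769%, and of the Polycomb gene Pcgf2 with 59.0 ± 1.48% and 83.3 ± 3.69%. Znhit1, Cnppd1 and Grwd1 differed by 39.5, 45.9 and 31.1 points. Lower levels were seen in Hspe1, which encodes the mitochondrial chaperonin Hsp10, with 75.4 ± 5.90% and 16.7 ± 0.984%, and in Twnk, which encodes the mitochondrial DNA helicase, with 88.4 ± 3.48% and 54.0 ± 2.70%. The trafficking genes Yif1b and Trappc5 differed by -44.8 and -47.9 points, and Bag5 and Tom1 by -37.6 and -18.8 points. These 12 bodies had 65 to 1219 reads per library. At shared CpGs the difference was 1.281 points in Vsig10l over 4 CpGs, 10.6 points in Eef1akmt3 over 3 and 0 points in Pcgf2 over 4. It was 9.65 points in Yif1b over 3 CpGs and -5.18 points in Tom1 over 8. Each of these bodies had at least 33 CpGs listed in every library, so the shared CpGs cover a small part of it. Of 20981 bodies tested on shared CpGs 0 were called, with 1142 at an unadjusted p under 0.05. The smallest adjusted p there, 0.0738, was that of Mrpl39, a mitochondrial ribosomal protein gene named after its values were seen, with 71.6 ± 1.84% in control and 47.9 ± 13.1% in FGR.

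The 14 gene lists were tested with limma's camera, which asks whether a list's members are higher or lower as a set, relative to other genes. Rises and falls within a list can cancel in this test. None passed for gene ends or gene bodies, and 0 of the lists passed with an estimated correlation or with fry's test of a shared direction. In fry's test of members that differ in either direction, 1 list passed at ends, the neuronal genes (adjusted p = 0.00581), and 1 in bodies, the inflammatory signalling genes (adjusted p = 0.000327). That test is too lenient here: of 10000 random lists of the same size 10.1% and 15.1% had a p under 0.05, and 0.31% and 0.08% a p as small as that of the list. These shares were computed after the results were seen. With control 1 and FGR 1 set against the rest, fry's p was 0.000401 for astrocyte bodies and 0.00360 for interferon bodies. In the real grouping fry's p was 0.000415 for neuronal ends and 2.34e-05 for inflammatory bodies. At ends the smallest p of the other splits was 0.0115, for disease-associated microglia with control 1 and FGR 2 against the rest. In the other splits neuronal ends and inflammatory bodies had p of 0.698 or more. Of 17065 genes with both ends measured the less methylated end was used. The median difference over all genes was -1.03 points at ends and -0.839 points in bodies. Over all genes 9303 of 17065 ends and 17015 of 28013 bodies were lower in FGR, the background for the counts below. At shared CpGs 11318 of 20981 bodies were lower. Of 19 measured ends of homeostatic microglia genes 11 were higher and 8 lower in FGR (adjusted p = 0.855), and of 26 bodies 9 were higher and 17 lower (adjusted p = 0.968). The low end of Siglech, a microglial lectin gene, had 82.5 ± 15.4% in control and 26.7 ± 18.9% in FGR, and the high end of Olfml3 had 56.9 ± 22.0% and 32.7 ± 12.2%. At shared CpGs 5 of 6 ends of the homeostatic microglia list were higher in FGR and 0 lower, with a median of 4.88 points, and the list passed there at an adjusted p of 0.0464. That test was added after the data were examined and holds 5 lists with at least 3 ends. Disease-associated microglia genes had 10 of 14 ends lower (adjusted p = 0.661, or adjusted p = 0.874 with an estimated correlation) and 12 of 19 bodies lower (adjusted p = 0.968). The low end of Cd83, an activation marker, had 52.1 ± 12.2% and 20.1 ± 8.26%, and the high end of Cd63, a tetraspanin gene, 55.6 ± 17.99% and 86.5 ± 12.4%. Adjusted over the list alone, 1 of its bodies was called, that of Apoe, the apolipoprotein E gene, with 26.4 ± 3.37% and 60.7 ± 5.43% over 132 to 475 reads. Apoe is named after its values were seen, and too few CpGs of its body were listed in all 4 libraries for a comparison on them.

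The complement and phagocytosis genes had 7 of 15 ends higher (adjusted p = 0.828) and 20 of 27 bodies lower in FGR (adjusted p = 0.729). At shared CpGs 19 of 23 of these bodies were lower, with a median of -2.20 points (adjusted p = 0.0969). Adjusted over the list alone, 1 of its ends was called, the low end of Megf10, an engulfment receptor gene, with 14.3 ± 6.57% in control and 64.0 ± 8.89% in FGR over 26 to 124 reads. The high end of Sirpa, the receptor of the signal CD47, had 23.0 ± 20.98% and 60.6 ± 6.77%. In the other lists 0 ends were called adjusted over the list alone, and 0 bodies outside the disease-associated list. Inflammatory signalling genes had 9 of 15 ends lower (adjusted p = 0.730) and 19 of 29 bodies lower (adjusted p = 0.968). The high end of Il6ra, an interleukin 6 receptor gene, had 67.4 ± 41.3% and 24.6 ± 6.53%, a difference of -13.5 points without control replicate 1 and -71.9 points without control replicate 2. The low end of Tnfrsf1a, a receptor of tumour necrosis factor, had 89.7 ± 5.68% and 58.6 ± 50.2%, where FGR replicate 2 decides the difference: it was 4.39 points without FGR replicate 2 and -66.6 points without FGR replicate 1. Interferon response genes had 7 of 14 ends lower (adjusted p = 0.828) and 17 of 19 bodies lower (adjusted p = 0.668). At shared CpGs 7 of 13 of these bodies were higher and 6 lower, with a median of 0.369 points (adjusted p = 0.906). The low ends of the interferon receptor gene Ifnar1 and of the signalling gene Stat2 differed by -32.6 and -32.5 points.

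Among hypoxia and glycolysis genes 5 of 10 ends were higher (adjusted p = 0.828) and 13 of 22 bodies lower (adjusted p = 0.729). The high end of Egln1 differed by -44.6 points and that of Ndrg1, a hypoxia-induced gene, by 26.4 points. For Egln1 it was -18.4 points without control replicate 1 and -70.7 points without control replicate 2. For Ndrg1 it was 15.3 points without FGR replicate 2. Glucocorticoid and growth signalling genes had 9 of 18 ends lower (adjusted p = 0.828) and 19 of 31 bodies lower (adjusted p = 0.968). The low ends of Tsc1, a restraint on mTOR, and of the circadian gene Per1 differed by -22.5 and 20.97 points. In the DNA methylation machinery 7 of 10 ends were higher (adjusted p = 0.887) and 12 of 18 bodies lower (adjusted p = 0.888). The high end of Gadd45a differed by -30.9 points, but by 5.27 points at shared CpGs, and the low end of Tdg, a DNA repair glycosylase gene, by 21.4 points, or -0.713 points in windows of 1000 bp on both sides. For Gadd45a FGR replicate 1 decides the difference: it was -1.41 points without FGR replicate 1 and -60.4 points without FGR replicate 2. Imprinted genes had 9 of 17 ends lower (adjusted p = 0.855) and 16 of 24 bodies lower (adjusted p = 0.729). The low ends of Peg10 and H13, both imprinted, had 74.95 ± 10.4% and 52.0 ± 4.54% in control and 39.9 ± 4.39% and 21.7 ± 3.41% in FGR.

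Markers of other cell types were tested in the same way. Neuronal genes had 8 of 13 ends higher (adjusted p = 0.828) and 14 of 17 bodies lower (adjusted p = 0.968), with differences of -24.7 points at the low end of Syt1, a synaptic vesicle gene, and -22.0 points at the high end of Grin1, a glutamate receptor gene. Astrocyte genes had 5 of 7 ends lower (adjusted p = 0.828) and 7 of 12 bodies lower (adjusted p = 0.968), with -32.1 points at the high end of the aldolase gene Aldoc and -27.5 points at that of Gfap. In the oligodendrocyte lineage 3 of 6 ends were higher (adjusted p = 0.828) and 9 of 13 bodies higher (adjusted p = 0.668), with -40.7 points at the high end of Myrf, a myelin regulator, and 35.2 points at the low end of Mbp, a myelin protein gene. For Myrf it was -15.1 points without control replicate 1 and -66.3 points without control replicate 2. Vascular genes had 5 of 7 ends higher (adjusted p = 0.828) and 8 of 13 bodies higher (adjusted p = 0.668). There the high end of Pecam1, an endothelial adhesion gene, differed by -22.8 points, and the low end of Vtn by -12.9 points, or by 3.95 points without FGR replicate 1. Markers of other leukocytes had 6 of 9 ends lower (adjusted p = 0.979) and 9 of 14 bodies lower (adjusted p = 0.968), with 19.8 points at the low end of Cd3g and -16.8 points at that of Cd3e, both T cell receptor subunit genes. For 18 of the 28 ends named from the lists, leaving out some single library raised or lowered the difference by more than a factor of 1.5, or reversed it. They were those of Gadd45a, Tdg, Aldoc, Sirpa, Cd63, Tsc1, Per1, Olfml3, Egln1, Ndrg1, Il6ra, Tnfrsf1a, Syt1, Grin1, Myrf, Cd3g, Pecam1 and Vtn. The sign of the median difference was opposite to that of the test at the ends of the complement, imprinted, interferon and other leukocyte lists, and in the bodies of the astrocyte, disease-associated, glucocorticoid and homeostatic lists. Camera's direction is relative to the other genes, and the median over all genes was -0.839 points in bodies. The astrocyte and glucocorticoid body medians, -0.208 and -0.599 points, lay above it, so they do not conflict with the test.

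Homeostatic microglia genes stood out by low body methylation in both groups. They had a median body level of 64.3% over the 4 libraries, against 77.7% over all 28013 genes. The central 95% of the medians of 10000 random lists with like numbers of CpGs ran from 74.1% to 82.7%, and 0% of them lay as low. Neuronal genes had a median of 69.3%, where random lists ran from 73.3% to 84.1%, and hypoxia and glycolysis genes 73.5%, where they ran from 74.1% to 83.3%. At gene ends the homeostatic microglia list had a median of 28.3%, against a range of 34.4% to 70.7%, the complement and phagocytosis list 27.6%, against 29.4% to 71.4%, and the glucocorticoid and growth signalling list 18.98%, against 30.4% to 70.6%. The random lists were added after the data were examined.

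**Figure D3:**
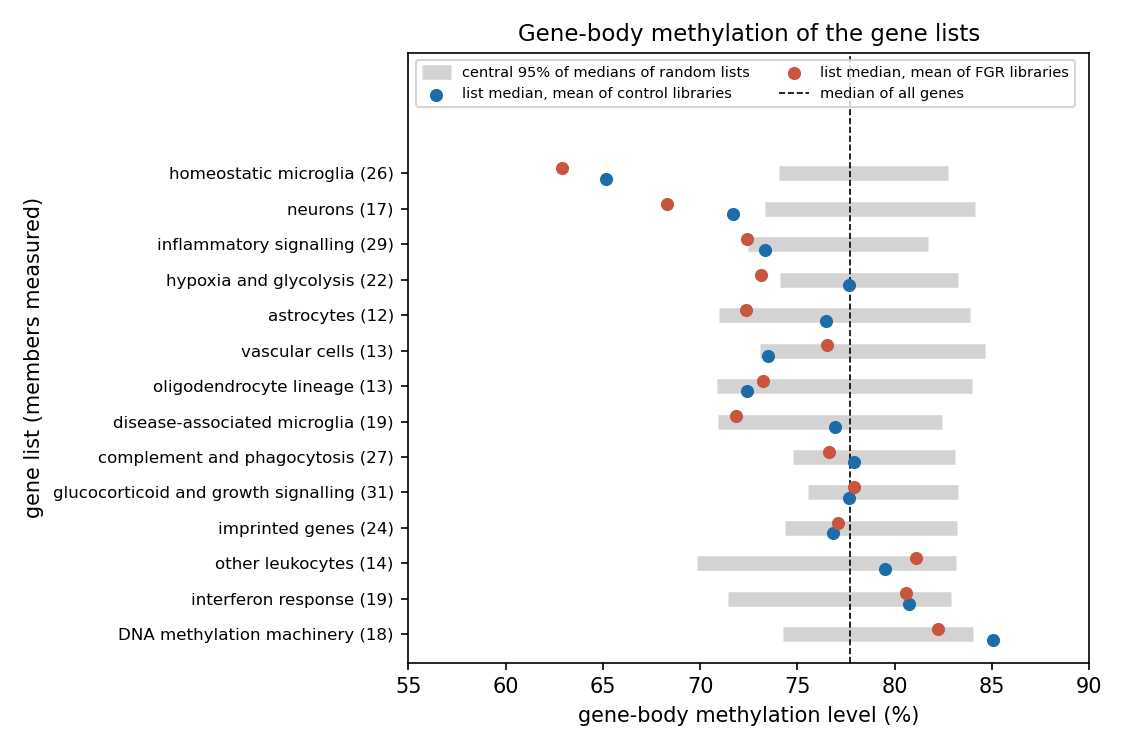
Median gene-body methylation level in percent of the 14 gene lists, with the number of members measured, as the mean of the control and of the FGR libraries (points), the central 95% of the medians of 10000 random lists (grey bars) and the median of all genes (dashed line). The homeostatic microglia list lies at 65.2% in control and 62.9% in FGR, below its grey bar, which starts at 74.1%.

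At single CpGs with at least 10 reads in every library 0 of 20262 sites were called by the quasi-binomial test, with 1071 at an unadjusted p under 0.05. With no filter on high coverage 43 of 30562 sites were called. On chromosome X, tested apart since the labels give no sex, 3 of 300 tiles were called. A pair of tiles in Mid1, a microtubule-associated ubiquitin ligase gene that spans the edge of the pseudoautosomal region, was more methylated in FGR. At 169978001 the level was 26.4 ± 7.90% in control and 73.96 ± 0.719% in FGR (adjusted p = 3.98e-08), and at 169981001 it was 54.9 ± 7.41% and 87.2 ± 2.67% (adjusted p = 8.02e-09). The tile at 5367001, 98904 bp from Mycs, had 84.2 ± 1.18% and 51.9 ± 7.41% (adjusted p = 0.0106). At 11 CpGs listed in all 4 libraries the second Mid1 tile differed by 0.692 points (adjusted p = 0.957), and of 210 X tiles tested on shared CpGs 0 were called, with 10 at an unadjusted p under 0.05. The level of chromosome X at shared CpGs was 68.7 ± 0.214% in control and 68.6 ± 0.552% in FGR.

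Libraries of a group resembled each other no more than libraries of different groups. Across 550656 tiles, which are not independent replicates, Pearson's r was 0.748 between the controls and 0.764 between the FGR libraries, and 0.731 to 0.777 between a control and an FGR library. The mean absolute difference of a tile was 9.56 points between the controls and 9.35 points between the FGR libraries, and 8.83 to 10.1 points between the groups.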

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

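The tests of the CpGs within called tiles, of the autosomal level by the level of neighbouring CpGs and without CpG-dense sequence, and of nuclear CpGs and nuclear copies for mitochondrial DNA were chosen only after the results were seen; the other splits and the autosomal level at shared CpGs had been planned, but the bounds that decide them were set afterwards, and the explanation tested by the share of CpG-dense sequence was narrowed, after its result, to the part of the difference that shared CpGs lack.

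A candidate explanation for the called tiles is that different CpGs of a tile were listed in the groups. Among the 152 of 162 called tiles with a CpG listed in both groups, the median difference in the direction of the call was 55.7 points over all CpGs and 6.38 points (quartiles 0.379 and 17.4) at CpGs listed in at least 1 library of each group, which is what differing CpG lists as a cause predict. Of the 107 tiles lower in FGR 81 had more CpGs listed in FGR, with medians of 9 in control and 14 in FGR, and of the 55 higher tiles 35 had fewer. The same share over all tested tiles was not computed, and FGR replicate 2 listed the most CpGs of any library. The real grouping called 162 tiles and the highest of the other splits 88, so of the 3 splits only the real one, 1 split, gave as many, and 3 splits are too few for a share under 0.05; on CpGs listed in all 4 libraries the real grouping called 1 tile and the other splits 4 and 3. A difference of growth-restricted microglia at part of these tiles remains open as untested. Among them are those in Rspo1, Abca2, Mbd2 and Cfap300 and near Gm41005 and Tex37.

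The lower autosomal level in FGR was weighed against listing and conversion. Different CpGs being listed cannot be the whole cause, since the level at shared CpGs still differed by -0.387 points, beyond the 0.153 points between libraries of a group. CpG-dense sequence is argued against as the cause of most of the part lost at shared CpGs, since without it the level still differed by -0.917 points, which removes 20.2% of that part; its share of listed CpGs, 0.0703 points higher in FGR with 1.43% and 1.34% in control and 1.59% and 1.32% in FGR, does not separate the groups. Loss of methylated cytosines in proportion to the level, on each cytosine apart, is argued against. Sequence whose neighbours are at 90% or more differed by only -0.158 points. This is less than the overall difference by more than the 0.110 points between the controls there. The neighbour level was taken from all 4 libraries and can include the same reads, so loss over whole molecules is not decided by it. A small genome-wide difference that goes with growth restriction may account for the -0.387 points at shared CpGs and stays open as untested, as do differences between animals or cell preparations, on which the labels are silent.

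Mitochondrial DNA, which the comparisons leave out, was more methylated in FGR, at 5.74% of 45933 reads in FGR replicate 1 (Wilson 95% interval 5.53% to 5.95%) and 2.88% of 80789 reads in FGR replicate 2 (2.77% to 3.00%), against 1.10% (0.996% to 1.21%) and 0.954% (0.875% to 1.04%) in the controls. These reads are counts summed over cytosines, so the intervals can be too narrow. The group means differed by 3.28 points (n = 2, exact permutation p = 0.333). Incomplete conversion across the genome that acts on each cytosine apart is argued against. Nuclear CpGs whose neighbours are under 5% methylated differed by -0.00293 points. The neighbour level was taken from all 4 libraries and can include the same reads. Molecules left unconverted as a whole would raise it and leave this class, so the value cannot decide on them. Nuclear copies of mitochondrial sequence are argued against by the fitted nuclear depth relative to mitochondrial coverage. It differed by -1.004 points, with 4.42% and 3.09% in control and 3.20% and 2.30% in FGR. Conversion failing on mitochondrial molecules alone cannot be told apart from true methylation: the rank correlation across positions was 0.413 between the FGR libraries and 0.0496 between the controls, which both explanations predict. Non-CpG cytosines, which would separate them, are not among the deposited values, and a difference of growth-restricted microglia stays open as untested.

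Chromosome Y, also outside the comparisons, had 73.1% in FGR replicate 1 (72.7% to 73.5%) and 71.7% in FGR replicate 2 (71.5% to 72.0%), above 69.8% in both controls (69.4% to 70.2% in each), while at the 314 Y CpGs listed in all 4 libraries the groups overlapped, with 78.6% and 80.6% in control and 79.98% and 81.6% in FGR.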

How the results depend on the processing

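The alternatives were fixed before the data were examined, except the tests of tiles, ends, bodies and lists on only CpGs listed in all 4 libraries, the left-out libraries for the autosomal level at shared CpGs and the autosomal level without CpG-dense sequence. The autosomal difference was negative throughout, from -1.53 to -0.573 points with each library left out, and smaller at shared CpGs, at -0.387 points by reads and -0.305 points with each CpG weighted equally. At shared CpGs it ran from -0.463 to -0.310 points with each library left out. The 162 called tiles became 16838 with no overdispersion, 21 at an adjusted p of 0.01, 83 at a coverage of 20, 77 with tiles of 300 bp, and 0 with 5 kb tiles, limma, centred levels or the replicate block, and 1 at shared CpGs. Left-out libraries gave 1558 to 1805 tiles, where moderation took the overdispersion as equal in all tiles. Of 18 named tiles 18 lost their call with limma, centred levels and the replicate block, 10 at an adjusted p of 0.01, 3 at a coverage of 20 and 1 when thinned, and the cause was not tested. The replicate numbers pair libraries by number alone, and their deviations correlated at 0.00209 across tiles, so the replicate block removes degrees of freedom and little else. On simulated data the block recovered no changed tile, so the calls lost with it carry no information. The 0 gene ends became 7233 with no overdispersion, 0 to 288 with each library left out and 1 at shared CpGs. The 0 bodies became 2273 with no overdispersion, and the 0 sites became 43 with no filter on high coverage. The 3 tiles of chromosome X became 7 with no overdispersion and 0 with the block and at shared CpGs. The 0 passing lists at gene ends became 1 at shared CpGs. Of 40 named ends 35, and of 12 named bodies 12, passed with no overdispersion. Lists with fewer than 3 ends at shared CpGs gave no value there. Single results turned direction as follows, and the cause was not tested. In 1000 bp windows the high end of Zbtb12 turned to 1.39 and the low end of Tdg to -0.713 points. At shared CpGs the body of Yif1b turned to 9.65 points over 3 CpGs. The high end of Gadd45a turned there to 5.27 points over 7 CpGs. With each library left out the low end of Tnfrsf1a ran from -66.6 to 4.39 points and that of Vtn from -29.7 to 3.95 points. Of 243 list results under the alternatives 45 turned direction, and none of these 45 passed in either direction. Their adjusted p with fry's test of a shared direction were 0.977 for the ends of the methylation machinery and homeostatic microglia, 0.844 for imprinted genes and 0.869 for other leukocytes, and in bodies 0.818 for astrocytes, 0.547 for disease-associated microglia, 0.665 for glucocorticoid signalling and 0.402 for homeostatic microglia. With the replicate block they were 0.975 for the bodies of disease-associated and homeostatic microglia and of inflammatory signalling. At shared CpGs they were 0.932 for the ends of imprinted, interferon and neuronal genes, 0.906 for the bodies of the methylation machinery, hypoxia, interferon and vascular lists, and 0.917 for glucocorticoid signalling. With each library left out, the adjusted p of lists that turned ran, at ends, from 0.577 to 0.931 for the methylation machinery, homeostatic microglia, hypoxia, oligodendrocyte and vascular lists, from 0.541 to 0.973 for astrocytes, from 0.604 to 0.931 for glucocorticoid signalling, from 0.819 to 0.956 for imprinted and interferon genes and from 0.714 to 0.956 for other leukocytes. In bodies it ran from 0.659 to 0.978 for the methylation machinery, disease-associated microglia, inflammatory and neuronal lists, from 0.594 to 0.806 for astrocytes, from 0.594 to 0.978 for glucocorticoid signalling, from 0.832 to 0.9999 for homeostatic microglia and from 0.659 to 0.865 for other leukocytes. At the coverage of these libraries and a change of 20 points, 0 of 50 simulated CpGs, 2 of 50 tiles and 47 of 50 gene bodies were recovered. The simulated overdispersion was near the 1.68 fitted to tiles, while gene bodies had 3.98 and single CpGs 1.10. The share of recovered bodies is therefore too high for these data, and 0 called bodies do not exclude such changes.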

Other observations

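Within the homeostatic microglia list the least methylated bodies included those of well-known microglial genes, which are named here after their values were seen. The body of P2ry13, a purinergic receptor gene, had 0% in control and 2.07% in FGR, and that of Aif1, which encodes the marker IBA1, had 26.0% in both groups. The bodies of Fcrls, an Fc receptor-like gene, had 31.2% and 30.4%, of Irf8, a myeloid transcription factor gene, 37.3% and 37.0%, and of Csf1r, the receptor of the survival factor CSF1, 41.9% and 41.4%.

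At CpGs listed in all 4 libraries the end with the second smallest p was the low end of Fastkd3, a gene of mitochondrial RNA processing on chromosome 13, with 67.4 ± 0.269% in control and 37.0 ± 3.51% in FGR over 55 to 81 reads, and it did not pass (adjusted p = 0.113). The low end of Apoe had 75.3 ± 4.65% and 90.8 ± 2.76% at 5 such CpGs (adjusted p = 0.891). Both were named after their values were seen.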
